A study of Rattus norvegicus with 8 samples.

How the data were processed

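RNA from laser-microdissected mammary cells of inbred female Sprague-Dawley rats was measured on 8 Agilent 1-colour arrays of rat oligonucleotides. Per the labels, rats aged 50 days received sesame oil or 20 mg of DMBA by stomach tube. Control TEB and DMBA TEB were collected at 64 days of age (2 weeks later), DCIS at 92 days (6 weeks) and MC at 106 days (8 weeks), with 2 arrays per group. The titles call the 6-week samples ductal carcinoma in situ, while their source field names an atypical ductal hyperplasia nodule, and the title is used here. The design text states repeated hybridisation of 4 samples, so the 2 arrays of a group are taken as repeats of 1 RNA sample, and p-values compare these RNA samples rather than conditions or animals. RNA was labelled with Cy3 after linear amplification, per the labels.

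Per the file headers, the deposited scanner outputs hold intensity values from Agilent Feature Extraction (version not stated), already background-subtracted and detrended within an array but not normalised between arrays. The authors' deposited value table holds a ratio of each array's scaled signal to the mean of the 2 control arrays, blank where a spot is not well above background, as checked on the values. The authors' deposited lists for 2, 6 and 8 weeks give a linear fold change against control with a 2-fold limit.

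Processed signals of non-control probes were divided by the array's 75th percentile, and spots marked as non-uniform or population outliers were left out. No gene probe was repeated on an array, so none was averaged over spots. All arrays received 1 common floor, a scaled signal of 0.0731 (−3.77 on the log2 scale), the highest of the lowest well-above-background signals of the 8 arrays, a rule set once the files were in hand. Of 20500 gene probes, 13188 were tested: those well above background on both arrays of at least 1 group. A fold is given as a lower bound where the lower group was well above background on neither array, against the mean of each such array's own lowest well-above-background signal (or the probe's own signal if higher), which lies at or below the common floor, and the number of arrays is stated where 1 of 2 was. Depth is given as signal over background: 11046 to 15125 probes per array were well above background, and saturated spots numbered 10 to 51 per array.

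Probes were named through the accessions and symbols of the RefSeq gene table for assembly GRCr8. Of the probes, 6544 were named by accession, 2888 by symbol, 2119 by an older symbol, 106 by description and 59 by the file's own name alone, and 8784 remained unnamed or carried a numbered locus. The tested probes hold 6609 named genes.

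Choices in this paragraph and the next were fixed before the data were examined. limma 3.58.1 in R 4.3.3 was fitted to 4 group means over all 8 arrays with empirical Bayes moderation. A probe was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1, in each of 5 comparisons: DMBA TEB, DCIS and MC against control TEB, DCIS against DMBA TEB, and MC against DCIS. Tests are two-sided except the term enrichment below.

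The 20 gene lists cover cell division and DNA replication, luminal epithelium, basal and myoepithelial cells, milk proteins and lactation, hormone receptors and response, aryl hydrocarbon receptor response and xenobiotic metabolism, p53 and DNA damage, growth factor, Wnt and oncogene signalling, extracellular matrix and fibroblasts, and matrix proteases and inhibitors. They also cover adipocytes, endothelium, myeloid and mast cells, lymphocytes, antigen presentation and interferon response, glycolysis and hypoxia, fatty acid and cholesterol synthesis, immediate early genes, skeletal muscle, and red blood cells and plasma proteins. Lists were tested with limma's camera at a preset correlation of 0.01, with 1 probe per gene (that of highest mean signal) and adjustment over 100 tests. Named genes are the 8 highest and 8 lowest called genes per comparison whose arrays do not overlap between groups, up to 2 called members of highest and up to 2 of lowest fold change per list, and 11 fixed genes. Some genes that meet this rule are not reported here. Counts adjusted over a list alone, where the 2-fold minimum still holds, were added later.

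Alternatives tried were normexp background correction (offset 50) on raw signals, quantile and median normalization, the authors' deposited values, no filter or a filter on all 8 arrays, keeping outlier spots, the replicate number as a block, only the 4 arrays compared, a mean-variance trend, treat, no fold minimum, a 2-fold difference in all 4 array pairs, and leaving out each array. Lists were also tested with an estimated correlation, with fry, against 10000 matched random lists and with the mean over a gene's probes. Blocking by nearness to the median background, by the array numbers of the authors' deposited workbook (which number the MC arrays the other way round) and by scanner slot, and a lower floor of 0.01, were added after the data were seen. Simulations of a shared control used 100 data sets. Terms of the authors' biological process annotation with 5 to 200 genes were tested for enrichment with Fisher's one-sided exact test among the named genes that could be called and carry a term. The procedure was tested on simulated data with 200 changed probes of 13188, of which 76% to 83% were recovered per comparison with 0 in the wrong direction and 2 to 12 false calls. The planted log2 changes were 1.5, 2, 3 or 4, and of those of 1.5, between 44.4% and 64.6% were recovered per comparison. Noise was drawn independently for each probe and array, without the floor or deviations shared between arrays, so these rates need not hold for the real arrays. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.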

Results

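Gene expression was measured in laser-microdissected rat mammary cells on 8 Agilent arrays, 2 for each of 4 groups. The groups were terminal end buds (TEB, the growing tips of the mammary ducts) of control rats, TEB of rats given 7,12-dimethylbenz[a]anthracene (DMBA, a chemical carcinogen), ductal carcinoma in situ (DCIS), and mammary carcinoma that had become invasive (MC). TEB were taken 2 weeks after treatment, DCIS 6 weeks and MC 8 weeks after it. The control arrays come from 2 weeks alone, so lesion stage runs together with age and with time since treatment. Of 20500 gene probes, between 53.9% (DMBA TEB replicate 1) and 73.8% (DCIS replicate 1) were well above background on an array, and the 75th percentile of signal ran from 156 to 728 intensity units on the same arrays. The number of arrays limits the precision of every value. Values after ± are standard errors of the log2 fold change from limma, with n = 2 arrays per group throughout. Where both arrays of a group lie at the common floor, the spread between them is hidden. Standard errors there can be too small, and calls that hold with an array left out can owe this partly to the floor. Among the genes below, this applies to Grp in both TEB groups, Orm1 in control TEB and DCIS, and Cdhr1 and Gzma in control TEB. It also applies to Defb1 in DCIS, to Adipoq, Fabp4, Ces1d and Pck1 in MC, and possibly to others.

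Across the 13188 probes tested, Pearson's r between the 2 arrays of a group was 0.979 for control TEB, 0.971 for DMBA TEB, 0.986 for DCIS and 0.969 for MC. These are correlations across probes, which are not independent replicates. Arrays of the same replicate number in control TEB and DMBA TEB lay closer to each other (0.983 and 0.990) than to the second array of their own group. MC replicate 1 also lay slightly closer to DCIS replicate 2 (0.970) than to MC replicate 2 (0.969). The first principal component held 42.1% of the variance and the second 23.6%. Because array background differed within groups, comparisons are also given within 2 sets of 4 arrays, each set holding 1 array per group. The near-median set has backgrounds of 131.6 to 134.9 intensity units and the other set backgrounds of 87.0 to 203.6, a split chosen after the data were seen. Where 2 values in brackets follow a list mean, they are its means in the near-median set and in the other set.

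**Figure D1:**
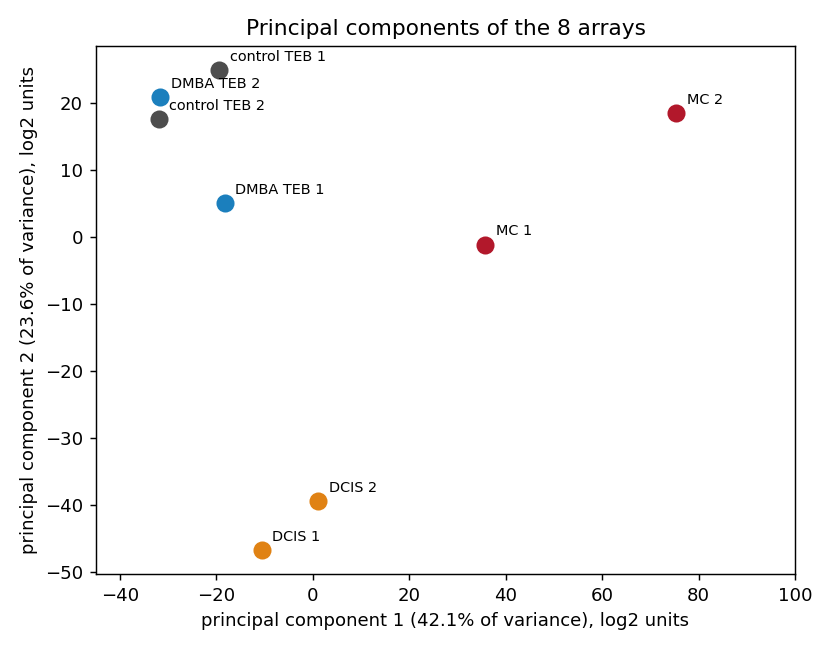
Positions of the 8 arrays on the first and second principal components of the scaled log2 signals (both axes in log2 units), each point 1 array labelled with its group and replicate. The axes hold 42.1% and 23.6% of the variance. The 4 TEB arrays lie together on the left, the DCIS arrays at the bottom and the MC arrays on the right.

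Of 100 tests, 20 gene lists in each of 5 comparisons, 32 had an adjusted p under 0.05 in limma's camera with its preset correlation of 0.01. With an estimated correlation 0 did, and the smallest adjusted p was 0.125, for lymphocyte genes in DMBA TEB. Of the 32 shifts, 20 held whichever array was left out. The lists share 0 genes with one another. List members named below that did not pass over all probes, or that passed but are not among the 2 highest or 2 lowest of their list, were chosen after their values were seen. The mean, median and test differed in sign in 10 of the 100 tests and in 0 of the 32 shifts. The 10 were aryl hydrocarbon receptor response in DCIS against control TEB, matrix proteases and skeletal muscle in MC against control TEB, milk proteins, antigen presentation and red blood cells in DCIS against DMBA TEB, and hormone receptors, p53, immediate early genes and red blood cells in MC against DCIS.

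**Figure D2:**
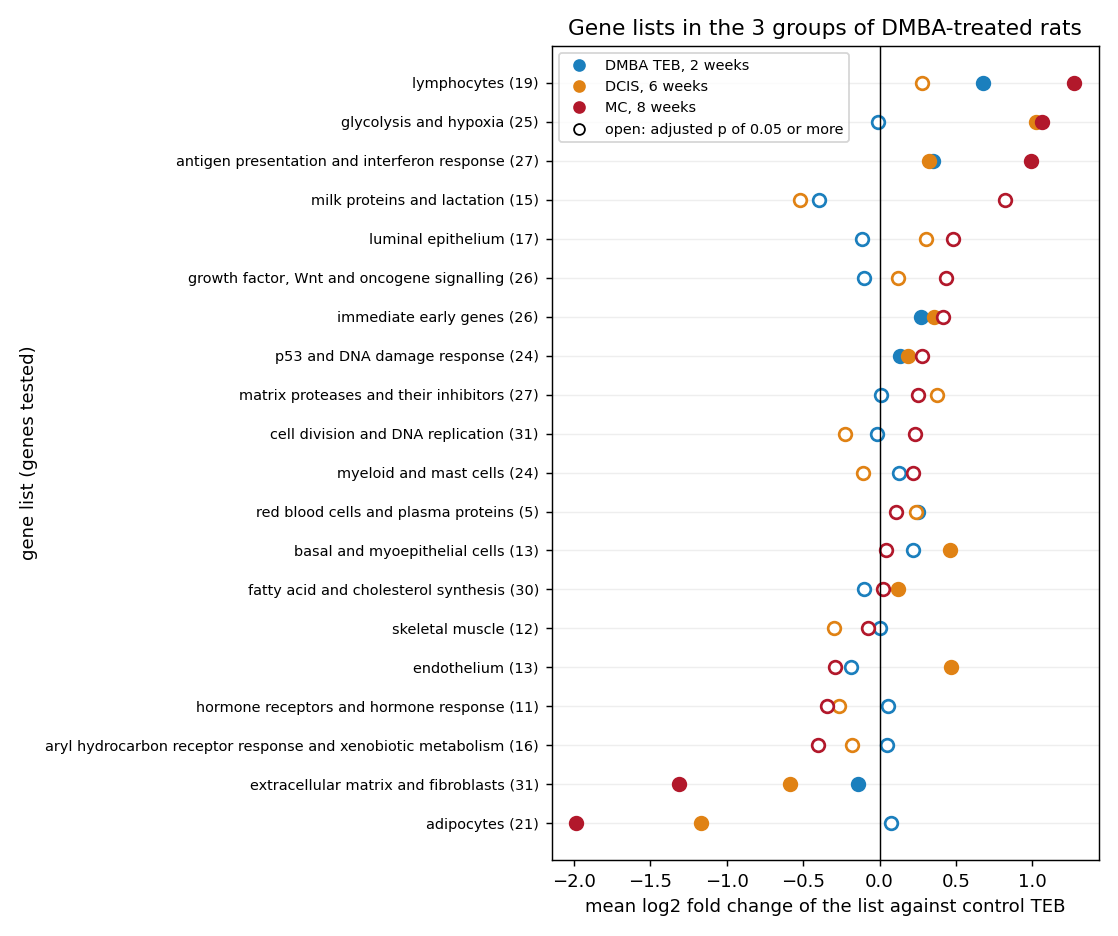
Mean log2 fold change against control TEB (horizontal axis) of each gene list (vertical axis, with the number of genes tested), for DMBA TEB, DCIS and MC. Filled points have a camera adjusted p under 0.05 at the preset correlation. The adipocyte list lies at −1.17 in DCIS and −1.98 in MC, and the lymphocyte list at 0.68 in DMBA TEB and 1.27 in MC.

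The comparison of DMBA TEB with control TEB asks how the end buds differed 2 weeks after the carcinogen. The lymphocyte list rose in DMBA TEB, with a mean log2 fold change of 0.68 [0.75, 0.61] over 19 genes (adjusted p = 4.34e-12, and adjusted p = 0.125 with an estimated correlation). None of its 19 members passed limma over all probes (0 higher, 0 lower), and adjusted over the list alone 7 were higher and 1 was lower. The higher ones include Cd3d (2.14 ± 0.28), a chain of the T cell receptor complex, Cd5 (2.05 ± 0.26) and the chemokine Ccl5 (2.33 ± 0.39), and the lower one is Cd52, a surface protein of mature lymphocytes (−2.43 ± 0.21). The antigen presentation and interferon list rose by a mean of 0.35 [0.41, 0.29] over 27 genes (adjusted p = 3.56e-06, and adjusted p = 0.265 with an estimated correlation). Over all probes 0 members passed, and adjusted over the list alone 1 was higher, the interferon-induced chemokine Cxcl10 (3.49 ± 0.37, with 1 of 2 control arrays well above background).

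The other lists with a shift at 2 weeks moved less. The immediate early list rose by a mean of 0.27 [0.41, 0.13] (adjusted p = 9.06e-04, and adjusted p = 0.273 with an estimated correlation). Its adjusted p was 0.0528 without control TEB replicate 1 and 0.246 without DMBA TEB replicate 1. The p53 and DNA damage list rose by 0.13 [0.12, 0.15] (adjusted p = 0.0275, and adjusted p = 0.265 with an estimated correlation), and its adjusted p was 0.0758 with normexp background correction. Its mean was 0.059 without control TEB replicate 1 and 0.045 without DMBA TEB replicate 2, and it did not pass in either case. The extracellular matrix list fell by 0.14 [−0.09, −0.19] (adjusted p = 0.0383, and adjusted p = 0.365 with an estimated correlation), and its adjusted p was 0.0620 with quantile normalization. Its mean was −1.31e-04 without control TEB replicate 2 and −0.049 without DMBA TEB replicate 1, and it did not pass in either case. No member of these 3 lists passed limma, either over all probes or adjusted over the list alone (0 in each).

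Among genes chosen beforehand, Cdkn1a, the p53 target that encodes the cell cycle inhibitor p21, had a log2 fold change of 0.72 ± 0.25 in DMBA TEB, and Cyp1b1, a DMBA-metabolising enzyme induced through the aryl hydrocarbon receptor, of −0.20 ± 0.27. Both have an adjusted p of 1. The progesterone receptor gene Pgr stood at 0.46 ± 0.68, the basal keratin gene Krt14 at 0.06 ± 0.37 with a second probe going the other way, and the casein gene Csn2 at −0.45 ± 0.83. The probes for Cyp1a1 and Esr1 were well above background on 0 of 8 arrays and were not tested, and Ccnd1, Mki67, Krt18 and Col1a1 were not analysed here for lack of a named probe.

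limma called 0 probes higher and 0 lower in DMBA TEB (281 of 13188, or 2.13%, had an unadjusted p under 0.05, and the smallest adjusted p was 0.391), while 21 probes were higher and 2 lower by at least 2-fold in all 4 pairs of arrays. The count was 0 with the background sets as a block, and 2 without control TEB replicate 2 or without DMBA TEB replicate 1. Both DMBA TEB arrays were read in a scanner slot that held no other group, so slot and treatment cannot be told apart. Log2 fold changes in the 2 sets had r = −0.0133 across probes, which are not independent replicates. Both arrays of a group are taken as repeat hybridisations of 1 RNA sample, so p-values here and in the comparisons below are too small for a comparison between animals.

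The comparison of DCIS with control TEB asks what set the first lesions apart from normal end buds. The secreted matrix metalloproteinase gene Mmp13 (collagenase 3) rose by 5.15 ± 0.19 on the log2 scale (adjusted p = 0.00814) and Mmp3 (stromelysin 1) by 3.61 ± 0.37. Spp1, which encodes the matrix glycoprotein osteopontin, rose by 3.08 ± 0.28, Slc16a3, a lactate exporter, by 3.49 ± 0.39, and Grp, gastrin-releasing peptide, was at least 40.8-fold higher because it was well above background on neither control array. Cbln2 fell by 3.99 ± 0.20 and the opioid precursor gene Penk by 3.33 ± 0.28. Of the other genes with the largest changes, Nell1 (3.33), Slc7a3 (3.16) and Aplnr (3.00) rose, and Nr2f1 (−3.33), Actn3 (−3.29), Slc1a3 (−2.80) and Adipoq (−2.78) fell, and Serpina3n was 7.99-fold lower.

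The glycolysis and hypoxia list rose in DCIS by a mean of 1.02 [1.13, 0.91] over 25 genes (adjusted p = 2.08e-11, and adjusted p = 0.188 with an estimated correlation). Over all probes 3 members rose (Slc16a3, the glycolytic enzymes Pfkp at 1.17 ± 0.14 and Aldoa at 1.14 ± 0.12) and 22 did not pass, and adjusted over the list alone 11 were higher and 0 lower. Vegfa stood at 2.46 ± 0.38 and the glucose transporter gene Slc2a1 at 1.73 ± 0.25. The adipocyte list fell by a mean of 1.17 [−1.07, −1.27] over 21 genes (adjusted p = 1.14e-06, and adjusted p = 0.265 with an estimated correlation), with 4 members lower and 17 not passing over all probes and 10 lower adjusted over the list alone. Adipoq (adiponectin) fell by 2.78 ± 0.24 and Fabp4, a fatty acid carrier of fat cells, by 2.49 ± 0.26. The extracellular matrix list fell by a mean of 0.58 [−0.46, −0.71] over 31 genes (adjusted p = 6.95e-04, and adjusted p = 0.273 with an estimated correlation). Its members Thbs2 (−2.38 ± 0.21) and Col6a3 (−1.82 ± 0.22) fell and 29 did not pass, and adjusted over the list alone 11 were lower and 1 higher, Ccn2 (3.48 ± 0.50), which encodes connective tissue growth factor.

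The endothelium list rose by a mean of 0.47 [0.45, 0.48] over 13 genes (adjusted p = 0.0162, and adjusted p = 0.336 with an estimated correlation), with an adjusted p of 0.0695 without DCIS replicate 2. Emcn (2.30 ± 0.20) and Plvap (2.20 ± 0.29), both surface proteins of vessel lining cells, rose and 11 did not pass, and adjusted over the list alone 4 were higher and 1 lower. The antigen presentation and interferon list rose by 0.33 [0.37, 0.28] (adjusted p = 0.00283, and adjusted p = 0.364 with an estimated correlation), and without DCIS replicate 2 its adjusted p was 0.130. In limma 0 of its 27 members passed over all probes and 1 was higher adjusted over the list alone. The immediate early list rose by 0.36 [0.35, 0.36] (adjusted p = 0.0162, and adjusted p = 0.342 with an estimated correlation), and without DCIS replicate 1 its adjusted p was 0.0917. Of its 26 members 1 rose over all probes, the heat shock gene Hspa1a (1.64 ± 0.20), and 2 were higher adjusted over the list alone. The basal and myoepithelial list rose by 0.46 [0.61, 0.31] (adjusted p = 0.0483, and adjusted p = 0.342 with an estimated correlation). Its adjusted p was 0.0523 with the background sets as a block, 0.185 without DCIS replicate 2, 0.0528 and 0.0595 without DMBA TEB replicate 1 and 2, 0.0861 and 0.0884 without MC replicate 1 and 2, and 0.0651 with the mean over a gene's probes. It had 0 of 13 members passing over all probes and 3 higher adjusted over the list alone: the smooth muscle genes Myh11 (3.03 ± 0.72) and Actg2 (1.02 ± 0.23) and the cadherin gene Cdh3 (1.39 ± 0.22).

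The p53 and DNA damage list rose by 0.19 [0.28, 0.10] (adjusted p = 0.0351, and adjusted p = 0.265 with an estimated correlation), and with normexp background correction, where the median of all probes stood at −0.21, it stood at −0.03 (adjusted p = 0.335). Its adjusted p was 0.0555 without control TEB replicate 1, and 0.0697 and 0.0592 without DCIS replicate 1 and 2. Over all probes 0 of its 24 members passed, and Cdkn1a (1.48 ± 0.25) was higher adjusted over the list alone. The fatty acid and cholesterol synthesis list rose by 0.12 [0.02, 0.23] (adjusted p = 0.04999, and adjusted p = 0.443 with an estimated correlation). Its adjusted p was 0.0593 with the background sets as a block, 0.345 without control TEB replicate 2, 0.0797 and 0.0867 without DMBA TEB replicate 1 and 2, 0.0585 and 0.152 without DCIS replicate 1 and 2, and 0.0703 with the mean over a gene's probes. It had 0 of 30 members passing over all probes and, adjusted over the list alone, 1 higher (Scd2, 1.39 ± 0.29) and 1 lower (Thrsp, −2.07 ± 0.32). In the lists without a shift, Cdkn2b, an inhibitor of cyclin-dependent kinases, rose by 2.37 ± 0.25 and the chemokine gene Ccl6 fell by 1.84 ± 0.22. Fixed genes that did not pass were Cyp1b1 (−1.08 ± 0.27), Cdkn1a (adjusted p = 0.0733), Pgr (−0.53 ± 0.68), Krt14 (−0.80 ± 0.37) and Csn2 (−0.48 ± 0.83). Second probes of Spp1, Aplnr, Cdkn2b and Cdkn1a lay at the floor in DCIS and in the TEB.

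limma called 96 probes higher and 76 lower in DCIS (172 of 13188), and 48 with the background sets as a block. Log2 fold changes in the near-median and the other set had r = 0.635 across probes. The count was 5 and 4 without control TEB replicate 1 and 2, 58 and 3 without DCIS replicate 1 and 2, and 92 without either MC array, and of the 25 genes named by the fixed rule that passed, 9 passed with the background sets as a block and 1 (Grp) passed whichever array was left out.

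**Figure D3:**
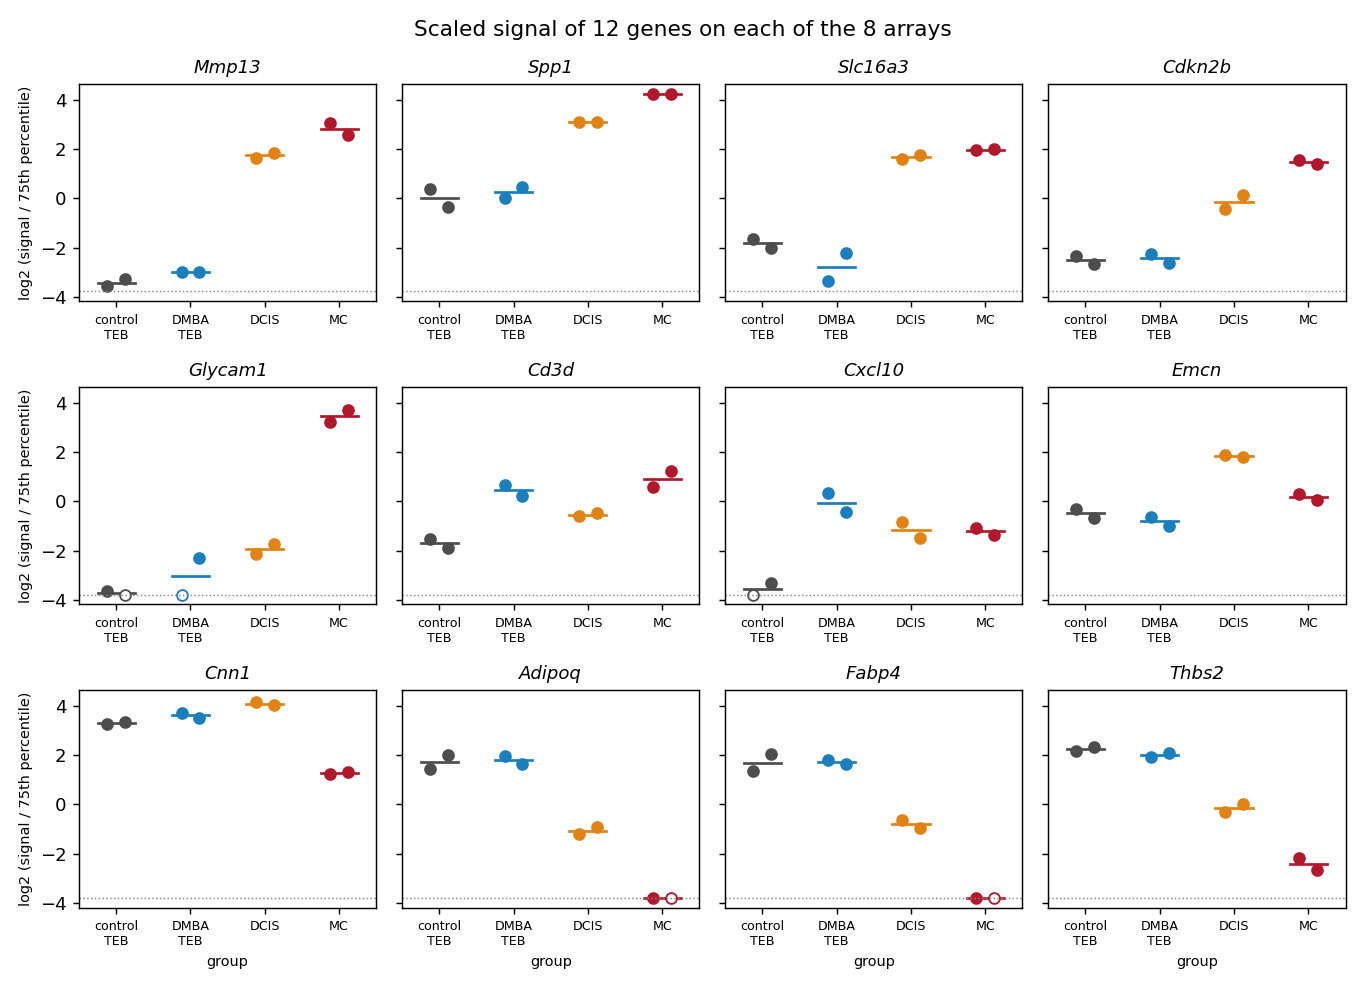
Scaled signal (vertical axis, log2 of signal over the array's 75th percentile) of 12 genes on each of the 8 arrays by group (horizontal axis). Points are arrays, short lines group means, and open points arrays where the probe was not well above background. The dotted line is the floor at −3.77, on which both MC arrays lie for Adipoq and Fabp4.

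The comparison of MC with control TEB asks how the invasive tumours differed from normal end buds. Glycam1, a mucin-like protein secreted into milk, rose by 7.15 ± 0.51 on the log2 scale, with 1 of 2 control arrays well above background. Mmp13 rose by 6.22 ± 0.19 (adjusted p = 9.78e-04), Spp1 by 4.23 ± 0.28, Mmp3 by 4.14 ± 0.37, Pcp4 by 5.57 ± 0.93 and Grp was at least 73.7-fold higher. Cdhr1 (5.17) and Orm1, an acute phase plasma protein (4.61), rose from control means at the floor, each well above background on 1 of 2 control arrays, so these values understate the change. Of fat cell genes, Adipoq fell by 5.50 ± 0.24 and Fabp4 fell by 5.46 ± 0.26. Both reached the floor in MC and were well above background on 1 of 2 MC arrays. Pck1 was at least 46.2-fold and Ces1d at least 36.3-fold lower. The bound for Pck1 is imprecise, since its log2 fold change at the common floor was −3.98 in the near-median set and −6.15 in the other set. Nr2f1 (−5.68) and Rbp4 (−4.95) fell with 1 of 2 MC arrays well above background, and Actn3 (−4.79) and Thbs2 (−4.65) fell with both.

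Of the 21 adipocyte genes tested, 13 fell in MC, 0 rose and 8 did not pass, with a list mean of −1.98 [−1.98, −1.99] (adjusted p = 1.22e-10, and adjusted p = 0.188 with an estimated correlation). Adjusted over the list alone 14 were lower and 1 higher, the thermogenic gene Ucp1, which was well above background on neither control array. The extracellular matrix list fell by a mean of 1.31 [−1.24, −1.38] over 31 genes (adjusted p = 7.71e-09, and adjusted p = 0.188 with an estimated correlation), with 9 lower and 22 not passing, and adjusted over the list alone 16 lower and 1 higher. Col5a1 (−3.54 ± 0.44), a fibrillar collagen gene, and Col6a3 (−3.31 ± 0.22) fell. The lymphocyte list rose by a mean of 1.27 [1.30, 1.24] over 19 genes (adjusted p = 1.40e-06, and adjusted p = 0.188 with an estimated correlation), with 5 higher and 14 not passing, and adjusted over the list alone 13 higher and 1 lower. Gzma, a protease of cytotoxic lymphocytes, rose by 3.95 ± 0.55 with 1 of 2 control arrays well above background, and Cd3d by 2.58 ± 0.28. The antigen presentation and interferon list rose by a mean of 0.99 [0.97, 1.02] over 27 genes (adjusted p = 2.21e-09, and adjusted p = 0.265 with an estimated correlation), with 5 higher and 22 not passing, and 10 higher adjusted over the list alone. Cxcl10 (2.32 ± 0.37, with 1 of 2 control arrays well above background) and Oasl (2.17 ± 0.36) rose.

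The glycolysis and hypoxia list rose in MC by a mean of 1.06 [0.99, 1.14] over 25 genes (adjusted p = 2.15e-09, and adjusted p = 0.188 with an estimated correlation), with 4 higher and 21 not passing, and 9 higher adjusted over the list alone. Slc16a3 rose by 3.80 ± 0.39 and the pyruvate kinase gene Pkm by 1.81 ± 0.28. Lists without a shift held members that went both ways. Of 27 matrix proteases and inhibitors, 4 rose (Mmp13, Mmp3, Mmp7 at 3.14 ± 0.42 and Mmp12 at 2.75 ± 0.27) and 5 fell (among them Ctsk at −3.09 ± 0.38, Mmp23 at −2.50 ± 0.31 with 1 of 2 MC arrays well above background, and Mmp14), while adjusted over the list alone 7 were higher and 6 lower. The list mean was 0.25, the median 0 and the direction of the test downward (adjusted p = 0.608). Among growth factor and oncogene signalling genes, Cdkn2b (3.99 ± 0.25), Fgf1 (1.67 ± 0.25) and Mycn (1.59 ± 0.21) rose and Igf1 (−1.57 ± 0.16) fell. The list mean was 0.44 (adjusted p = 0.0559, adjusted p = 0.0441 with the background sets as a block, and adjusted p = 0.274 with an estimated correlation and no block). Cell markers also split: Tspan8 rose (1.82) and Cldn1, a tight junction gene, fell (−2.67) in the luminal list, Cdh3 rose (1.98) and Cnn1, the smooth muscle calponin gene, fell (−2.01) in the basal list, and Lyz2 rose (1.30) and Ccl6 fell (−2.38) in the myeloid list.

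Cdkn1a, at 1.75 ± 0.25 (adjusted p = 0.0329), was the member of the p53 list that rose, and Tiparp, a target of the aryl hydrocarbon receptor, fell by 1.97 ± 0.26. Ramp2 of the endothelium list fell by 1.88 ± 0.26, with 1 of 2 MC arrays well above background. Cyp1b1 (−0.13 ± 0.27), Pgr (−0.53 ± 0.68), Krt14 (0.56 ± 0.37) and Csn2 (−0.66 ± 0.83, with 1 of 2 MC arrays well above background) did not pass. Mean log2 fold changes of the other lists in MC were 0.82 for milk proteins (adjusted p = 0.305), 0.48 for luminal epithelium (0.0850), 0.04 for basal and myoepithelial cells (0.745), 0.28 for p53 and DNA damage (0.188), 0.23 for cell division (0.185), 0.41 for immediate early genes (0.182) and 0.02 for fatty acid and cholesterol synthesis (0.817). They were 0.22 for myeloid and mast cells (0.140), −0.29 for endothelium (0.745), −0.34 for hormone receptors (0.146), −0.40 for the aryl hydrocarbon receptor list (0.0926), 0.11 for red blood cells and plasma proteins (0.608) and −0.08 for skeletal muscle (0.824), whose median was 0.39 and whose test pointed upward.

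limma called 183 probes higher and 236 lower in MC (419 of 13188), 287 with the background sets as a block and 190 with normexp background correction. Log2 fold changes in the near-median and the other set had r = 0.529 across probes, and the 5 list shifts held whichever array was left out. The count was 100 and 87 without control TEB replicate 1 and 2, 184 without either DCIS array, and 684 (415 higher and 269 lower, so that more rose than fell) and 121 without MC replicate 1 and 2. Of the 37 genes named by the fixed rule that passed, 26 passed with the background sets as a block and 12 passed whichever array was left out (Actn3, Adipoq, Cdkn2b, Ces1d, Cnn1, Fabp4, Grp, Mmp13, Nr2f1, Orm1, Spp1 and Thbs2).

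DCIS and MC were both compared with the same control arrays, and their log2 fold changes had r = 0.459 across probes, which are not independent replicates. Simulated data in which neither lesion differed from the controls gave a mean r of 0.4995 from the shared control alone, with a covariance of 0.0630 against 0.202 observed. Of the DCIS calls, 34 were also higher and 66 also lower in MC (58.1%) and 0 went the opposite way. Independent lists of these sizes would share 1.33 and 1.36, and the simulated data shared 0.01 and 0. The first of these values leaves out the shared controls and the second the effects. Simulated noise was drawn independently for each probe and array from the spread between arrays of a group. It holds no floor, no deviations shared between arrays and no spread between control RNA samples. The simulated covariance and shared calls can therefore understate what a shared control gives. The 2 control arrays cannot be split so that each lesion keeps 2 of its own, so part of this overlap can come from them.

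The comparison of DCIS with DMBA TEB asks what separated the 6-week lesions from treated end buds. Mmp13 rose by 4.72 ± 0.19 (adjusted p = 0.0126), Slc16a3 by 4.45 ± 0.39, Nell1 by 3.47 ± 0.43, Mmp3 by 2.98 ± 0.37 and Spp1 by 2.85 ± 0.28, and Grp was at least 37.5-fold higher. Aplnr (2.96) and Rgs5, a marker of vessel-associated cells (2.84), rose with 1 of 2 DMBA TEB arrays well above background. Actn3 (−3.38), Cbln2 (−3.18), Nr2f1 (−2.91), Adipoq (−2.86), Penk (−2.69), Slc1a3 (−2.63) and Fabp4 (−2.54) fell.

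The glycolysis and hypoxia list rose by a mean of 1.03 [1.10, 0.96] (adjusted p = 4.11e-13, and adjusted p = 0.188 with an estimated correlation), with 2 members higher and 23 not passing, and 8 higher adjusted over the list alone. Aldoa rose by 1.28 ± 0.12. The adipocyte list fell by a mean of 1.25 [−1.42, −1.07] (adjusted p = 2.77e-07, and adjusted p = 0.265 with an estimated correlation), with 4 lower and 17 not passing, and 11 lower adjusted over the list alone. The endothelium list rose by a mean of 0.65 [0.61, 0.69] (adjusted p = 0.00149, and adjusted p = 0.265 with an estimated correlation). Emcn (2.63 ± 0.20) and Plvap (2.43 ± 0.29) rose, 11 did not pass, and 4 were higher adjusted over the list alone. The extracellular matrix list fell by a mean of 0.45 [−0.37, −0.52] (adjusted p = 0.00742, and adjusted p = 0.336 with an estimated correlation), with Thbs2 (−2.15 ± 0.21) and Fbln5 (−1.52 ± 0.20) lower and 29 not passing, and adjusted over the list alone 6 lower and 1 higher. With normexp background correction its adjusted p was 0.0562. The fatty acid and cholesterol synthesis list rose by a mean of 0.23 [0.24, 0.21] (adjusted p = 0.00283, and adjusted p = 0.342 with an estimated correlation), with 1 member higher, the sterol synthesis gene Cyp51 (1.20 ± 0.14), 29 not passing, and 2 higher adjusted over the list alone.

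The luminal epithelium list rose by a mean of 0.42 [0.31, 0.53] (adjusted p = 0.00925, and adjusted p = 0.310 with an estimated correlation), with 0 of 17 members passing over all probes and 0 adjusted over the list alone. The lymphocyte list fell by a mean of 0.40 [−0.37, −0.44] (adjusted p = 0.0205, and adjusted p = 0.265 with an estimated correlation), with 0 of 19 passing over all probes and, adjusted over the list alone, Cd52 higher (1.11 ± 0.21) and Cd8b lower (−1.11 ± 0.23). Without DMBA TEB replicate 2 the luminal list had an adjusted p of 0.145 and the lymphocyte list 0.0927. Without DCIS replicate 2 the luminal list had 0.0592, and without DCIS replicate 1 the lymphocyte list had 0.0511. In lists without a shift, Cdkn2b rose by 2.28 ± 0.25 and Ccl6 fell by 1.96 ± 0.22. Cyp1b1 (−0.88 ± 0.27), Cdkn1a (0.76 ± 0.25), Pgr (−0.99 ± 0.68), Krt14 (−0.86 ± 0.37) and Csn2 (−0.03 ± 0.83) did not pass.

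limma called 78 probes higher and 58 lower (136 of 13188), and 1 with the background sets as a block. Log2 fold changes in the near-median and the other set had r = 0.501 across probes. The count was 12 without either control TEB array, 83 and 14 without DMBA TEB replicate 1 and 2 (the 14 being 4 higher and 10 lower), 62 and 3 without DCIS replicate 1 and 2, and 54 without either MC array, and of the 24 genes named by the fixed rule that passed, 1 passed with the background sets as a block and 1 (Grp) passed whichever array was left out.

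The comparison of MC with DCIS asks what changed between the in situ and the invasive stage. Glycam1 rose by 5.38 ± 0.51 (adjusted p = 0.0234), Orm1 by 4.61 ± 0.12 from a mean at the floor, Cbln2 by 3.89 ± 0.20 and the complement gene C3 by 3.55 ± 0.26. Cdhr1 (3.75), Megf6 (3.08) and Tmprss6 (2.78) rose, as did Defb1, an epithelial defensin gene (2.80, with 1 of 2 DCIS arrays well above background). Myh11, smooth muscle myosin, stood at −4.97 ± 0.72 with 1 of 2 MC arrays well above background, and Cnn1 at −2.80 ± 0.11 (adjusted p = 0.00543). Acsm3 (−4.38), Spef2 (−3.28), Rbp4 (−3.13), Fabp4 (−2.97) and Anpep (−2.81) fell, each with 1 of 2 MC arrays well above background, Popdc2 (−2.81) fell with both, and Ces1d was at least 10.0-fold lower.

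The lymphocyte list rose from DCIS to MC by a mean of 0.99 [0.92, 1.07] (adjusted p = 8.54e-05, and adjusted p = 0.188 with an estimated correlation), with 2 members higher and 17 not passing, and 10 higher adjusted over the list alone. Cd52 rose by 2.52 ± 0.21 and Cd3g, a chain of the T cell receptor complex, by 1.75 ± 0.15. The antigen presentation and interferon list rose by a mean of 0.67 [0.60, 0.74] (adjusted p = 2.19e-04, and adjusted p = 0.334 with an estimated correlation), with 0 of 27 passing over all probes and 4 higher adjusted over the list alone, among them Irf7 (1.40 ± 0.22) and Cd74 (1.21 ± 0.25). The adipocyte list fell by a mean of 0.81 [−0.91, −0.72] (adjusted p = 1.54e-05, and adjusted p = 0.265 with an estimated correlation), with 4 lower and 17 not passing, and adjusted over the list alone 7 lower and 1 higher. The extracellular matrix list fell by a mean of 0.73 [−0.79, −0.67] (adjusted p = 2.02e-05, and adjusted p = 0.265 with an estimated correlation), with 5 lower and 26 not passing, and 8 lower adjusted over the list alone. Dcn, the proteoglycan decorin, fell by 2.51 ± 0.37 and Thbs2 fell by 2.27 ± 0.21. The endothelium list fell by a mean of 0.76 [−0.99, −0.53] (adjusted p = 2.19e-04, and adjusted p = 0.265 with an estimated correlation), with Emcn lower (−1.64 ± 0.20), 12 not passing, and 4 lower adjusted over the list alone.

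The cell division list rose by a mean of 0.46 [0.42, 0.49] over 31 genes (adjusted p = 0.0279, and adjusted p = 0.525 with an estimated correlation), with 0 passing over all probes and 3 higher adjusted over the list alone: Ccna2 (1.46 ± 0.31), Ube2c (1.05 ± 0.22) and Cdc20 (1.01 ± 0.19). Its adjusted p was 0.0922 without DCIS replicate 2, 0.151 without MC replicate 1 and 0.357 with normexp background correction. In lists without a shift, Mycn rose by 2.28 ± 0.21, Mmp12 by 2.01 ± 0.27 and Lyz2 by 1.45 ± 0.22, and Actn3 fell by 1.51 ± 0.21. Krt14 (1.35 ± 0.37, adjusted p = 0.123), Cyp1b1 (0.95 ± 0.27), Cdkn1a (0.27 ± 0.25), Csn2 (−0.18 ± 0.83, with 1 of 2 MC arrays well above background) and Pgr (−0.00 ± 0.68) did not pass.

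limma called 85 probes higher and 142 lower (227 of 13188), 54 with the background sets as a block and 18 with normexp background correction (9 higher and 9 lower). Log2 fold changes in the near-median and the other set had r = 0.585 across probes. The count was 56 without either control TEB array, 73 and 75 without DCIS replicate 1 and 2, and 645 and 34 without MC replicate 1 and 2 (393 higher and 252 lower, and 24 higher and 10 lower, so that in both more rose than fell), and of the 26 genes named by the fixed rule that passed, 8 passed with the background sets as a block and 4 (Cbln2, Cnn1, Defb1 and Orm1) passed whichever array was left out.

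The authors' deposited table of 2-fold changes against control lists 63 probes at 2 weeks, 798 at 6 weeks and 981 at 8 weeks, and all of them went the same way in the values recomputed here. The probes in the authors' deposited table that differed by at least 2-fold here numbered 60, 751 and 873, and 0, 113 and 285 of them were called by limma. Lists in the authors' deposited table were chosen on these same arrays, so they are not independent evidence of direction. For T cell genes at 2 weeks, chosen after their values were seen, the authors' deposited table gives a fold of 4.32 for Cd3d, 4.05 for Cd5 and 4.93 for Ccl5, and a ratio of 0.181 for Cd52.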

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

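The tests of explanations in this part were chosen after the results were seen, except the test of dim probes, while the tests of MC against DCIS were planned. The results listed first had effects of opposite sign in DCIS and MC against the same control TEB, and the difference between the lesions passed its own test in limma. The effects against control TEB were not required to pass. Over all probes Myh11 passed in neither lesion. Other effects that did not pass include Cnn1, Mycn, Cd52, Acsm3 (1.44 ± 0.66) and Popdc2 (1.24 ± 0.36) in DCIS. In MC they include Tmprss6 (1.00 ± 0.37) and Megf6 (0.57, under the minimum of 1). In camera the endothelium list did not pass in MC (adjusted p = 0.745), nor the cell division list in DCIS or MC (adjusted p = 0.146 and 0.185).

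Myh11 stood at 3.03 in DCIS and −1.94 in MC, a difference of −4.97 ± 0.72 (adjusted p = 0.0454), and Cnn1 at 0.79 and −2.01, a difference of −2.80 ± 0.11 (adjusted p = 0.00543). Acsm3 (1.44 and −2.94, difference −4.38), Spef2 (1.89 and −1.39, difference −3.28) and Popdc2 (1.24 and −1.57, difference −2.81) went the same way, where Myh11, Acsm3 and Spef2 were well above background on 1 of 2 MC arrays. Megf6 (−2.52 and 0.57, difference 3.08), Tmprss6 (−1.78 and 1.00, difference 2.78), Mycn (−0.68 and 1.59, difference 2.28) and Cd52 (−1.33 and 1.19, difference 2.52) went the other way. The endothelium list had a mean of 0.47 in DCIS and −0.29 in MC, a difference of −0.76 (adjusted p = 2.19e-04, and adjusted p = 0.265 with an estimated correlation). The cell division list had means of −0.22 and 0.23, a difference of 0.46 (adjusted p = 0.0279, and adjusted p = 0.525 with an estimated correlation). Within each background set the cell division means of DCIS and MC had the same sign, 0.05 and 0.47 in the near-median set and −0.50 and −0.01 in the other. Of these 9 genes, Cnn1 passed MC against DCIS whichever array was left out.

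The adipocyte list was lower in DCIS (−1.17) and MC (−1.98), with Adipoq at a scaled log2 signal of 1.72 in control TEB, −1.06 in DCIS and −3.77, the floor, in MC, where 1 of 2 arrays was well above background. A smaller share of all cells outside the epithelium would lower every such list alike. As the whole cause in DCIS it is argued against by the endothelium list, which rose (mean 0.47) and lay 1.64 log2 above the adipocyte list. In MC the gap was 1.69, but the median of the endothelium list was 0. Genes at the floor in both groups cannot fall, so in MC this cause stays open. Standard errors over genes were 0.43 in DCIS and 0.57 in MC. Genes are not independent replicates, and these errors hold no spread between arrays. The extracellular matrix and fibroblast list fell too (−0.58 and −1.31), so a smaller share of fat cells and fibroblasts together stays open. Fewer fat cells in the dissected material and lower expression within the cells cannot be told apart, since the count of 14 of 21 adipocyte genes at least 2-fold lower in MC (66.7%) restates the fall. The greater age of the rats with lesions was not tested and stays open.

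The lymphocyte list had a mean of 0.68 in DMBA TEB and 1.27 in MC, which did not pass with an estimated correlation (adjusted p = 0.125 and 0.188), and 0.28 in DCIS (adjusted p = 0.0780, with 4 members higher and 2 lower adjusted over the list alone), and in DMBA TEB 0 of 19 members passed limma over all probes and Cd52 stood at −2.43. A single array as the source is argued against by the lowest mean of this list over all array pairs, 0.58. T cell RNA in the dissected material and a change within resident cells cannot be told apart. Of 11 T and NK cell genes, picked after the list values were seen, 8 (72.7%) were at least 2-fold higher in DMBA TEB and 10 (90.9%) in MC, which restates the rise. The carcinogen and, for MC, age were not tested as explanations and stay open. So do a control RNA sample low in lymphocyte genes, since all 3 groups were set against the same one, and the scanner slot for DMBA TEB. The array pairs share that control sample and slot, so they test neither.

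Control TEB and DMBA TEB arrays of the same replicate number deviated from their group means together, with r = 0.476 across probes, which are not independent replicates. Noise of dim probes is argued against by r = 0.405 over the brightest probes. An array batch marked by background level, shared by TEB and DCIS arrays, stays open, since the lowest correlation among these groups with arrays ordered by background, 0.253, restates those by replicate number with the DCIS arrays exchanged. Whether MC arrays share this batch stays open, since the highest correlation with the MC arrays was 0.0788, too small to decide either way. No biological explanation was tested for this pattern.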

How the results depend on the processing

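Blocking by background, workbook number or scanner slot and the lower floor were chosen after the data were seen, and all other alternatives were planned. Named genes that passed kept their direction under every alternative in which their probe was tested. For each count below that differs from the one reported by over 1.5 times the cause was not tested, except that fewer arrays or probes were used where stated. In order of DCIS, MC (each against control TEB), DCIS against DMBA TEB and MC against DCIS, limma called 58, 158, 51 and 78 probes with no filter, which tests more probes, 0, 57, 0 and 0 with only the 4 arrays compared, and 3, 81, 2 and 4 with treat. A 2-fold difference in all 4 array pairs, with no p-value, held for 520, 653, 346 and 598 probes and for 23 in DMBA TEB. With probes well above background on all 8 arrays, 1 was called in DMBA TEB, 343 in DCIS, 210 for DCIS against DMBA TEB and 436 for MC against DCIS, and in MC 293 rose and 285 fell. Normexp gave 58 higher and 61 lower in DCIS, 190 in MC and 18 for MC against DCIS, and put the median log2 fold change of all probes at −0.21 in DCIS, 0.16 in MC, −0.23 for DCIS against DMBA TEB and 0.33 for MC against DCIS.

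The replicate number as a block left 1, 264, 1 and 77 calls and an adjusted p of 0.0629 for the basal list in DCIS, although deviations of same-numbered arrays correlated positively in control and DMBA TEB (0.476) and negatively between these and DCIS (−0.287 and −0.253), so the numbers do not pair all groups. The authors' deposited workbook numbers the MC arrays the other way round, which would exchange the values without MC replicate 1 and 2, and its numbers as a block left 2, 249, 2 and 51. The background block, which puts MC replicate 2, the array of highest background (203.6), with those of low background and so does not follow the level in MC, left 48 in DCIS, 1 for DCIS against DMBA TEB and 54 for MC against DCIS. It took the basal and the fatty acid synthesis list in DCIS above 0.05 and brought 3 other lists under it, luminal epithelium in DCIS (adjusted p = 0.0389), growth factor signalling in MC (0.0441) and milk proteins for MC against DCIS (0.0496). With an estimated correlation and no block, camera gave these 3 lists adjusted p of 0.364, 0.274 and 0.552. Slide or scan date as a block was not run, since the files used give neither. File names give a scanner slot. Within the slot that holds control TEB, each lesion has 1 array, where limma called 0 in DCIS, 376 in MC (259 higher and 117 lower) and 306 for MC against DCIS (214 higher and 92 lower), and these counts do not test the slot.

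With 1 array left out, the group left with 1 array is assumed to vary like the others. Calls then ranged from 0 to 2 in DMBA TEB, 3 to 192 in DCIS, 87 to 684 in MC, 3 to 83 for DCIS against DMBA TEB and 34 to 645 for MC against DCIS, and list shifts from 26 to 40. The cell division list in DMBA TEB moved from −0.02 to 0.27 without control TEB replicate 2 and to −0.30 without control TEB replicate 1. Of 32 list shifts, 0 held with an estimated correlation. By their median, 52 lists lay in the tails of matched random lists, a limit not adjusted for the number of tests, and 29 of the 32 were among them. Those not among them were p53 in DMBA TEB and DCIS and cell division in MC against DCIS. The fry test, which sets a list against no change rather than against other genes, passed 33, of which 23 were among the 32. Those of the 32 that did not pass in fry were antigen presentation in DMBA TEB (adjusted p = 0.144) and DCIS (0.151), immediate early genes in both (0.189 and 0.118), extracellular matrix in DMBA TEB (0.329), fatty acid synthesis in DCIS against control TEB (0.222) and DMBA TEB (0.0997), luminal epithelium in DCIS against DMBA TEB (0.1003) and cell division in MC against DCIS (0.109). Called shares of probes in the authors' deposited table were 14.3% with normexp and 45.0% with all 4 array pairs, against 21.6% reported. The lower floor moved the within-group array correlation from 0.976 to 0.956 and called 106 higher and 43 lower in DCIS, of which 91 were among the 172 reported, 78 and 37 for DCIS against DMBA TEB and 42 and 167 for MC against DCIS. Signal over background limits what the dimmest genes can show, since 53.9% to 73.8% of probes were well above it.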

Other observations

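The tests of biological process terms below were chosen after the data were seen and cover 577 terms of the authors' annotation in 4 comparisons and both directions (4616 tests). Of these, 5 passed at an adjusted p under 0.05. Genes annotated to neuropeptide signalling were enriched among those higher in DCIS, with 5 of 39 called genes against 31 of 4956 in the background (adjusted p = 0.0156, Fisher's exact test): Adgrl3, Adgrl4, Cpe, Grp and Npy. The opioid precursor gene Penk went the other way in DCIS (−3.33). The DCIS calls depend strongly on single arrays, as given above, and terms were not tested with an array left out. Immune response genes were enriched among those higher in MC, with 11 of 101 called genes (adjusted p = 0.0268, Fisher's exact test), among them Gzma, Cxcl10, Ccl17 and Ltb.

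The term peptidoglycan metabolic process held 4 genes higher in MC (adjusted p = 0.0451, Fisher's exact test), Mmp3, Mmp7, Mmp12 and Mmp13, which are known as proteases of the extracellular matrix. Among genes lower in MC, homophilic cell adhesion held 6 of 110 called genes (adjusted p = 0.0451, Fisher's exact test), among them Cdh13, Pcdh18 and Ret. Receptor tyrosine kinase signalling also held 6 (adjusted p = 0.0451, Fisher's exact test): Col1a2, Cspg4, Fn1, Pcsk5, Pdgfra and Pdgfrb. Pdgfra and Pdgfrb encode the receptors for platelet-derived growth factor. Col1a2, Fn1, Pdgfra and Pdgfrb also belong to the extracellular matrix and fibroblast list, so this term partly restates the fall of that list.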
